A study of Columba livia with 12 samples.

How the data were processed

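Total RNA was extracted with Trizol from frozen breast muscle of White-King pigeons (Columba livia) at the ages of 1D, 14D, 28D and 2Y, with 3 libraries per stage, and sequenced on an Illumina platform, per the labels. Per the submitters' processing notes, STAR 2.6.0c and Cufflinks 2.1.1 were used, and neither the role of each tool, the genome build, the annotation nor the method of computing expression values is given in the sources used here. The authors deposited 2 tables of TPM, one of mRNA genes with 12918 entries and one of lncRNAs with 9158 entries, and the authors' deposited TPM was used without change unless stated. The file names give a TPM limit for each table whose rule is not stated. Over the 9 libraries used, the highest value of an entry was as low as 0.137 TPM in the mRNA table and 0 in the lncRNA table. The deposited TPM of both tables together summed to nearly the 1000000 TPM of a whole library (991186 to 993735 TPM), so a larger share in one table lowers the values of the other. TPM keeps no count of reads, so the depth of each library is unknown and no counting interval was computed.

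Each table had 12 value columns. The names of 9 matched the stage and replicate of a sample title, and the other 3 columns carried a name that matches no label and were not used in any step. The 2Y comparisons that were planned were therefore not analysed here, and the design, planned for 12 libraries and 4 stages, was run on 9 libraries and 3 stages. A comparison of 28D with 1D was added after the column names were seen. No pair of libraries had identical values. Identifiers were matched to symbols with the supplied RefSeq gene table of the assembly bColLiv1.pat.W.v2, which was not named by the authors. In the mRNA table, 12256 of 12918 identifiers were found there, 1315 of them with placeholder symbols. Of the lncRNA entries 5492 carried an NCBI gene ID and 3666 another name, and 1604 were found, of which the reference calls 1382 lncRNA, 218 protein-coding and 4 something else. No identifier was duplicated, so no values were summed. Positions are those of the reference table.

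Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2(TPM + 1) for mRNA genes with at least 1 TPM in at least 3 of the 9 libraries (11951 genes) and on log2(TPM + 0.1) for lncRNAs with at least 0.1 TPM in at least 3 libraries (8685 transcripts), with 1 mean per stage. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 within the comparison, and the moderated F test over the 3 stages used the same threshold. All tests were two-sided except where stated. Resemblance of libraries was measured as the mean Spearman correlation within stages minus that between stages, tested over all 280 splits. Gene lists were written before the data were examined: fast-fibre sarcomere, slow and embryonic sarcomere, myogenic regulators, cell cycle, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, tricarboxylic acid cycle, fatty acid oxidation, glycolysis and glycogen, regulators of oxidative genes, collagens and matrix, the insulin-like growth factor and myostatin axis, atrophy and autophagy, proteasome, ribosomal proteins, circadian clock, cholesterol and lipid synthesis, and immediate-early and heat shock genes, and markers of endothelial cells, smooth muscle and pericytes, fibroblasts, adipocytes, macrophages, lymphocytes, red blood cells, and nerve and Schwann cells. Each list was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists, and beside it with camera at an estimated correlation. No call of any list held with the estimated correlation, and the lowest such adjusted p was 0.0599. The fry test, which asks whether the members move one way and compares them with no other genes, was run as an alternative.

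Genes were named by a rule fixed before the data were examined. For each comparison it took the 5 largest rises and 5 largest falls among called genes with a symbol, with at least 5 TPM in the higher stage and no overlap between the libraries of the 2 stages, up to 4 called members of each list with the largest change (or, where none was called, up to 2 with the highest mean), a fixed set of muscle and growth genes whatever their result, and in the lncRNA table the 3 largest rises and 3 largest falls with at least 1 TPM in the higher stage and no overlap. With 3 libraries against 3, chance alone keeps the libraries of a gene from overlapping in 10% of genes. Of the fixed set, PVALB, FABP4, CKM, LDHA and LDHB were not among the tested symbols. Genes named outside the rule are stated to have been named after their values were seen. Text on a list gives its most informative named members.

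The test was checked on simulated data with the measured spread and 200 planted changes per table. Of 100 log2 changes of 1 and 100 of 2 it recovered 60 and 89 in the mRNA table (9 false calls among 158). Among the lncRNAs it recovered 5 and 33 (3 among 41), so most were missed. Recovery with more changes was not tested. Alternatives fixed before the data were examined were another pseudocount (0.1 for mRNA, 1 and 0.01 for lncRNA), no filter or a stricter filter (5 TPM for mRNA, 1 TPM for lncRNA), libraries rescaled by their median ratio to the mean library, quantile normalization, only the 6 libraries of the stages compared, robust eBayes, arrayWeights, the replicate number as a block, joint adjustment over the comparisons, a fold change of at least 2, and leaving out each library in turn. Chosen after the data were seen were TPM set to 1000000 within the mRNA table, leaving out the 100 most abundant features of both tables, quantile normalization for the list tests, and the library resemblance with each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.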

Results

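The breast muscle of White-King pigeons, a meat breed of the domestic pigeon, was profiled by RNA sequencing in birds at day 1 after hatching (1D), day 14 (14D) and day 28 (28D), and in adults aged 2 years (2Y), with 3 libraries per stage. The comparisons asked which messenger RNAs and long noncoding RNAs (lncRNAs) differ in abundance between stages of muscle development after hatching. Values were the authors' deposited TPM (a length-scaled share of all transcripts) in separate tables for mRNA genes and for lncRNAs, and 9 of the 12 libraries, those of 1D, 14D and 28D, could be matched by name to a column. TPM keeps no record of sequencing depth, so library depth and counting error are unknown. The mRNA table summed to 841238 ± 4657 TPM at 1D, 756387 ± 26855 TPM at 14D and 778740 ± 14882 TPM at 28D (mean ± SD, n = 3), and the remainder lay almost entirely in the lncRNA table, whose share was 15.4% ± 0.473 at 1D, 23.7% ± 2.7 at 14D and 21.5% ± 1.51 at 28D (SD, n = 3). Means below are given in TPM with their SD over the 3 libraries of a stage, and log2 changes are those of TPM plus the pseudocount. The labels do not state that each library came from a separate bird, so the p-values measure the spread between libraries.

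Libraries of the same stage resembled each other more, on average, than libraries of other stages. The mean Spearman correlation across mRNA genes was 0.971 within stages and 0.879 between stages, a difference of 0.0921, and the real grouping gave the highest difference among all 280 splits of the 9 libraries into 3 groups of 3 (exact permutation, one-sided p = 0.00357, the smallest these splits can give). The highest difference of another split was 0.088, and the lowest correlation within a stage, 0.96, lay below the highest between stages, 0.963. The stages were unevenly spaced. The mean correlation was 0.862 between 1D and 14D, 0.956 between 14D and 28D and 0.819 between 1D and 28D. The F test over the 3 stages called 6985 of 11951 mRNA genes, of which 4987 had their highest mean at 1D, 613 at 14D and 1385 at 28D. The share with the highest mean at 1D was 71.4% of these genes and 47.1% of the other tested genes. After median-ratio rescaling the F test called 6669 genes, with shares of 49.5% and 38.7%. That rescaling centred the mRNA genes by construction (median log2 change 0.01 for 14D vs 1D) but left the lncRNAs at -0.17. In the lncRNA table the F test called 2286 of 8685 transcripts, of which 1719 had their highest mean at 1D, 184 at 14D and 383 at 28D. Here the share at 1D was 75.2%, against 51.1% of the other transcripts, and after rescaling 58.4% of 2070 called transcripts, against 44.7%. Without 1D replicate 1, 2 or 3 the lncRNA count was 1050, 1082 or 1126.

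**Figure D1:**
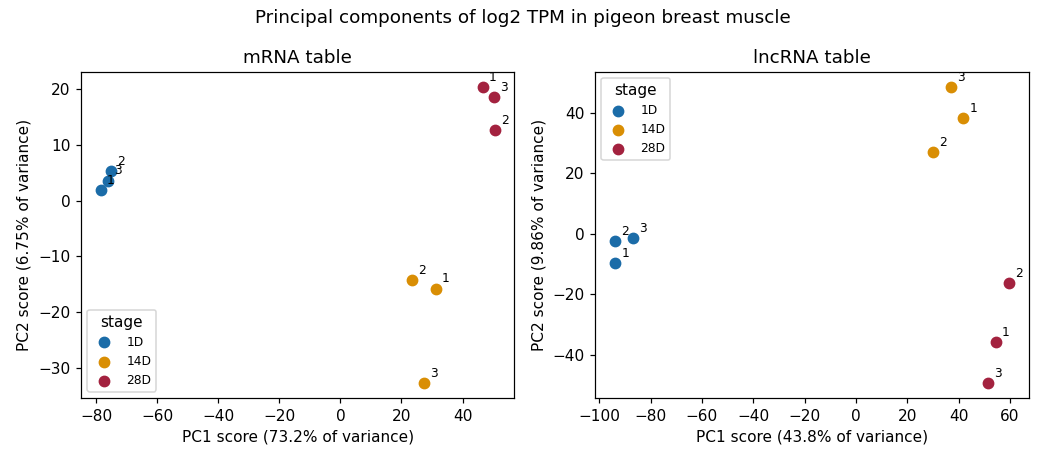
Scores of the 9 libraries on the first and second principal components of the log2 TPM values, for mRNA genes (left) and lncRNAs (right); each point is 1 library, coloured by stage and numbered by replicate. The first component carried 73.2% of the variance in the mRNA table and 43.8% in the lncRNA table, and the 1D libraries lay apart from those of 14D and 28D on it.

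Between day 1 and day 14 the muscle lost transcripts of slow and embryonic-type contractile proteins, of dividing cells and of the connective tissue matrix, and gained transcripts of glycogen and sugar metabolism. MYBPC1, the slow-type myosin-binding protein C (gene ID 102090756, chromosome 1 from 149198327 to 149273937 in the reference annotation), fell from 1404 ± 206 to 25.4 ± 35.2 TPM (log2 change -6.77, adjusted p = 8.32e-05). GPD1, the cytosolic glycerol-3-phosphate dehydrogenase (gene ID 102088900, chromosome 29 from 1932673 to 1941264), rose from 2.31 ± 1.56 to 305 ± 45.1 TPM (log2 change 6.62, adjusted p = 3.5e-07). CDK1, the kinase that drives entry into mitosis, fell from 127 ± 11.6 to 19.4 ± 6.07 TPM. COL1A1, a chain of type I collagen, fell from 2329 ± 389 to 381 ± 49.4 TPM (n = 3 per stage for each).

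Among the largest rises between these stages, besides GPD1, were those of MYLK4, a myosin light chain kinase (0.595 ± 0.105 to 52.5 ± 8.68 TPM), and PPP1R3C, which targets a protein phosphatase to glycogen (1.94 ± 0.0508 to 95.5 ± 16.9 TPM). DGAT2, an enzyme of triacylglycerol synthesis, rose from 1.74 ± 1.63 to 88.2 ± 58 TPM and PCMTD1 from 3.81 ± 1.1 to 137 ± 34.9 TPM. The largest falls were those of HBAD, a haemoglobin alpha chain of birds (312 ± 94.9 to 0.732 ± 0.664 TPM), MYBPC1, DYDC1 (109 ± 31.1 to 0.737 ± 0.646 TPM), THBS4, a matrix glycoprotein (81.4 ± 24.6 to 0.361 ± 0.129 TPM), and PTN, the secreted growth factor pleiotrophin (156 ± 42.5 to 2.1 ± 1.6 TPM). In each of these 10 genes all libraries of the higher stage lay above those of the lower, as the naming rule required.

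In total, 6311 of 11951 mRNA genes passed the test between 14D and 1D, 1623 higher and 4688 lower at 14D, and 727 of the higher and 2293 of the lower changed at least 2-fold. The median log2 change of all tested genes was -0.31, and after rescaling each library by its median ratio that median was 0.01. The rescaled values gave 2931 higher and 3100 lower genes, and quantile normalization 2964 and 3140. Both methods centre the libraries on each other, so the rescaling brings the median close to 0 by construction, and the balance of higher and lower genes is no evidence on the cause of the excess of lower genes. List medians of the comparisons with 1D are therefore given as deposited and also relative to the median of all genes.

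**Figure D2:**
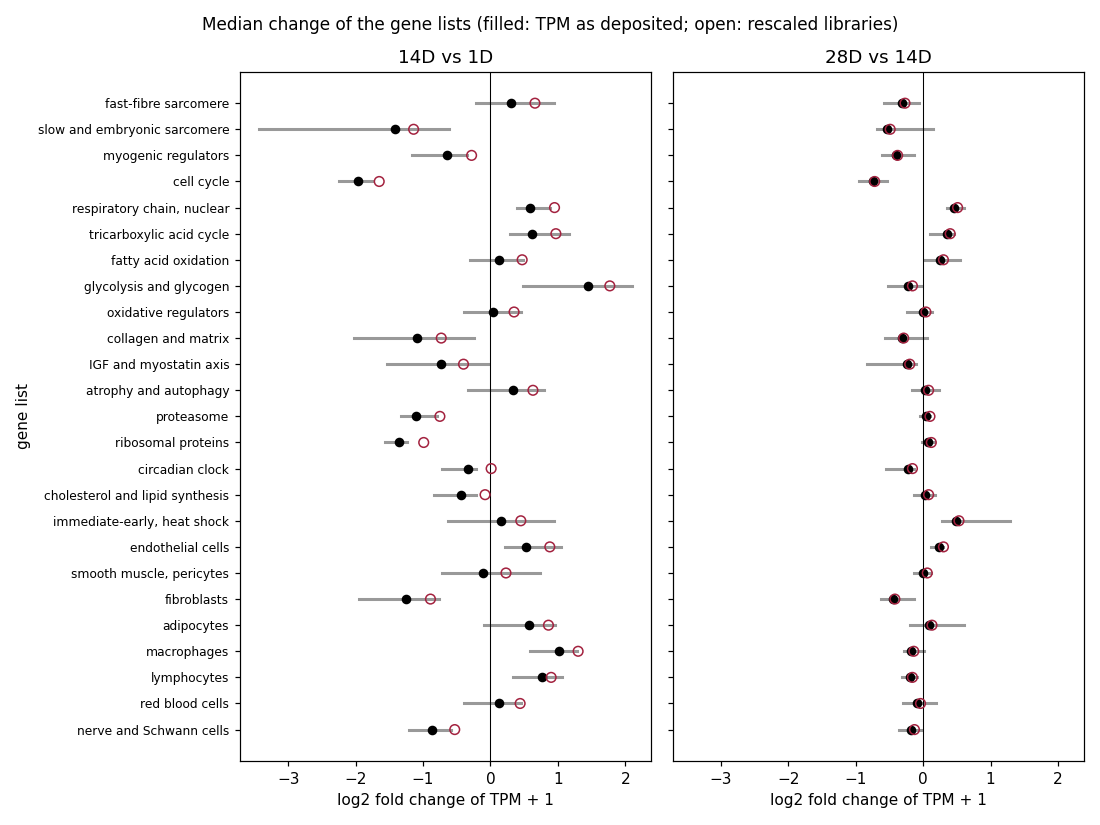
Median log2 change of TPM + 1 of each gene list (vertical axis) for 14D vs 1D (left) and 28D vs 14D (right); filled points are deposited TPM, open points are libraries rescaled by their median ratio, and grey bars span the middle of the members from the lower to the upper quartile. The cell cycle list has the lowest median in both panels, -1.97 and -0.75, while the circadian clock and smooth muscle medians for 14D vs 1D lie below 0 as deposited and above 0 after rescaling.

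Genes of DNA replication and mitosis fell almost as a block from 1D to 14D. Of 60 measured members 59 fell and 0 rose, with 1 higher and 59 lower after rescaling. Their median was -1.97 (-1.66 relative to all genes), and 59 members were lower also when adjusted over the list alone. RRM2 and TYMS, enzymes of deoxynucleotide supply, fell from 100 ± 25.4 to 10.2 ± 2.74 TPM and from 36.4 ± 3.36 to 3.99 ± 2.46 TPM. PLK1, a mitotic kinase, fell from 38.2 ± 0.5 to 5.46 ± 1.74 TPM. The list moved down against other genes (camera adjusted p = 1.44e-15, adjusted p = 0.231 with an estimated correlation). Ribosomal proteins fell in 62 of 64 members and rose in 1, with 2 higher and 61 lower after rescaling. Their median was -1.35 (-1.04 relative to all genes), with 62 also adjusted over the list alone (camera adjusted p = 4.12e-13, adjusted p = 0.268 with an estimated correlation). RPL5 fell from 1960 ± 119 to 535 ± 57.9 TPM, RPSA from 2059 ± 176 to 581 ± 64.4 TPM and RPL11 from 2858 ± 293 to 844 ± 138 TPM. RPL3L, the striated-muscle paralogue of RPL3, rose from 5.9 ± 2.87 to 168 ± 31.9 TPM. Proteasome subunits fell in 28 of 31 members and rose in 1, with 1 higher and 25 lower after rescaling. Their median was -1.11 (-0.80 relative to all genes), with 29 lower when adjusted over the list alone (camera adjusted p = 1.99e-07, adjusted p = 0.231 with an estimated correlation). PSMA5 fell from 397 ± 46.9 to 114 ± 12.4 TPM, PSMA2 from 127 ± 13.8 to 39.2 ± 2.31 TPM, PSMC1 from 277 ± 23.7 to 87.9 ± 10.8 TPM and PSMC5 from 189 ± 17 to 67.9 ± 1.46 TPM.

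Among contractile genes, slow, cardiac-type and embryonic isoforms mostly fell, with 12 of 19 measured members lower and 2 higher at 14D than at 1D (2 higher and 13 lower when adjusted over the list alone), with 3 higher and 11 lower after rescaling. Their median was -1.41 (-1.10 relative to all genes). MYL3, a slow myosin light chain, fell from 43.8 ± 4.07 to 0.465 ± 0.282 TPM and TNNI1, the slow troponin I, from 156 ± 67.7 to 4.33 ± 0.662 TPM. The risers were ANKRD1, a stress-responsive ankyrin repeat protein (13.2 ± 4.31 to 339 ± 270 TPM), and TNNC1, the slow and cardiac troponin C, named after its values were seen (822 ± 441 to 3799 ± 1414 TPM). The list moved down (camera adjusted p = 0.0282, adjusted p = 0.231 with an estimated correlation), with an adjusted p of 0.0811 without 1D replicate 3. The fast-fibre list, of sarcomere and calcium-handling genes, had 17 of 33 entries measured and no myosin heavy chain. Of the 17, 7 rose and 2 fell, also when adjusted over the list alone, with 12 higher and 1 lower after rescaling. Their median was 0.30 (0.61 relative to all genes). RYR1 and RYR3, calcium release channels, rose from 63.5 ± 5.48 to 219 ± 80.3 TPM and from 21.3 ± 6.28 to 59.2 ± 11.8 TPM. MYOZ1, a Z-disc protein, rose from 544 ± 180 to 1424 ± 116 TPM. TPM2, the beta tropomyosin, fell from 2837 ± 253 to 322 ± 67.4 TPM. The fast-fibre list moved up (camera adjusted p = 0.0022, 0.231 with an estimated correlation and 0.111 after quantile normalization). TNNT3, the fast troponin T, had 4866 ± 727 and 5707 ± 787 TPM and did not pass (adjusted p = 0.27, or 0.0233 and higher at 14D after rescaling).

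Of 30 myogenic regulators 14 fell and 0 rose from 1D to 14D (13 adjusted over the list alone). Their median was -0.64 (-0.33 relative to all genes). After rescaling 11 were lower and 2 higher. NES, the intermediate filament nestin, fell from 298 ± 83.6 to 26.5 ± 6.34 TPM, EYA1 from 29 ± 12 to 4.01 ± 1.19 TPM and CDH15, the cadherin of muscle precursors, from 90.1 ± 19.1 to 24.3 ± 5.94 TPM. MEF2C, a transcription factor of muscle differentiation, fell from 349 ± 79.1 to 115 ± 17.6 TPM. The list did not pass against other genes (camera adjusted p = 0.102, with 0.0449 without 1D replicate 2 and 0.0395 without 14D replicate 1). The myogenic factors themselves did not pass: MYOG had 13.3 ± 8.72 and 9.96 ± 4.9 TPM (adjusted p = 0.555) and MYF5 31.4 ± 12.5 and 21.7 ± 3.93 TPM (adjusted p = 0.139). MYOD1 had 203 ± 64.3 and 129 ± 40.7 TPM (adjusted p = 0.088, with 0.0184 without 1D replicate 2 and 0.0416 without 14D replicate 1). PAX7, the satellite cell factor, fell from 8.07 ± 1.02 to 5.03 ± 1.27 TPM (adjusted p = 0.0205), but its adjusted p was 0.27 after rescaling, 0.075 without 1D replicate 1, 0.0594 without 1D replicate 2 and 0.0619 without 14D replicate 2.

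In the insulin-like growth factor and myostatin axis 21 of 37 members fell and 2 rose (22 and 3 when adjusted over the list alone), with 3 higher and 16 lower after rescaling. Their median was -0.74 (-0.43 relative to all genes). The fetal RNA-binding proteins IGF2BP1, IGF2BP2 and IGF2BP3 fell from 22.5 ± 1.72 to 1.49 ± 0.909, from 42.1 ± 5.33 to 4.23 ± 1.35 and from 30.8 ± 3 to 3.55 ± 1.11 TPM, and HMGA2, a chromatin protein of growing tissue, from 8.55 ± 2.01 to 0.236 ± 0.123 TPM. IGF1 fell from 27.1 ± 10.8 to 3.9 ± 0.43 TPM (adjusted p = 0.000181). MSTN, the growth inhibitor myostatin, had 74.7 ± 33.5 and 72.5 ± 21.8 TPM and did not pass (adjusted p = 0.926). The list moved down (camera adjusted p = 0.0282, adjusted p = 0.231 with an estimated correlation), with 0.0787 without 14D replicate 2.

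Transcripts of several branches of energy metabolism rose from 1D to 14D. Glycolysis and glycogen genes rose in 21 of 30 members and fell in 2 (21 and 3 when adjusted over the list alone), with 24 higher and 1 lower after rescaling. Their median was 1.45 (1.76 relative to all genes), which passed against other genes (camera adjusted p = 1.54e-13, adjusted p = 0.0599 with an estimated correlation). PGM1, phosphoglucomutase, rose from 105 ± 12.6 to 776 ± 66.3 TPM and ALDOC, an aldolase, from 268 ± 4.75 to 1469 ± 254 TPM. Nuclear-encoded respiratory chain subunits rose in 26 of 40 members and fell in 0, also when adjusted over the list alone, with 36 higher and 0 lower after rescaling. Their median was 0.58 (0.89 relative to all genes, camera adjusted p = 4.69e-13, adjusted p = 0.231 with an estimated correlation). NDUFV1, NDUFS1 and NDUFS8, subunits of complex I, rose from 332 ± 11.3 to 768 ± 128, from 203 ± 18.9 to 421 ± 79.4 and from 294 ± 29.4 to 593 ± 36.4 TPM. NDUFB6 rose from 96.1 ± 33.5 to 522 ± 528 TPM, with 1131 TPM in 14D replicate 1. Tricarboxylic acid cycle genes rose in 15 of 24 members and fell in 1, also when adjusted over the list alone, with 20 higher and 0 lower after rescaling. Their median was 0.61 (0.91 relative to all genes, camera adjusted p = 2.96e-09, adjusted p = 0.231 with an estimated correlation). PDK2, a kinase that restrains pyruvate dehydrogenase, rose from 18.1 ± 5 to 102 ± 23.8 TPM, SUCLA2 from 107 ± 4.76 to 450 ± 75.8 TPM, SUCLG1 from 94.2 ± 5.37 to 238 ± 26.5 TPM and OGDH from 153 ± 19.1 to 361 ± 17 TPM. The transcripts encoded by the mitochondrial genome had 0 measured members.

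Fatty acid oxidation genes split, with 5 of 36 members higher and 6 lower at 14D than at 1D (the same counts adjusted over the list alone), a median of 0.12 (0.43 relative to all genes), a mean of -0.07 and a camera call upward (adjusted p = 0.0282, adjusted p = 0.483 with an estimated correlation), with 0.0985 without 14D replicate 1 and 0.0541 without 14D replicate 2. After rescaling 17 were higher and 5 lower. The fallers included ACSL3 and ACSL6, which activate fatty acids (26.4 ± 2.47 to 3.88 ± 1.08 and 4.47 ± 1.51 to 1.66 ± 0.228 TPM), SLC27A6, a fatty acid transporter (1.75 ± 0.261 to 0.443 ± 0.113 TPM), and FABP3, the muscle fatty acid-binding protein (2280 ± 515 to 709 ± 732 TPM, adjusted p = 0.0135, or 0.0516 after quantile normalization). CPT1A had 31.3 ± 8.65 and 31.4 ± 4.13 TPM (adjusted p = 0.919) and LPL 123 ± 17.2 and 125 ± 51.9 TPM (adjusted p = 0.85), and neither passed. MB, the oxygen store myoglobin, rose from 68.7 ± 17.6 to 1483 ± 2219 TPM (adjusted p = 0.0325), but its adjusted p was 0.0838, 0.0794 and 0.0576 without 1D replicate 1, 2 and 3. Among 21 regulators of oxidative genes 4 rose and 5 fell, also when adjusted over the list alone, and 10 were higher and 2 lower after rescaling. Their median was 0.04 (0.35 relative to all genes, camera up, adjusted p = 0.0368, adjusted p = 0.326 with an estimated correlation), with 0.0755 without 1D replicate 3 and 0.0742 without 14D replicate 1. PRKAG3, a muscle subunit of AMP-activated kinase, rose from 7.85 ± 2.05 to 51.5 ± 3.03 TPM, ESRRB from 5.6 ± 0.838 to 23.2 ± 3.35 TPM and ESR1 from 0.303 ± 0.105 to 3.05 ± 0.524 TPM. PPARA fell from 40.6 ± 7.24 to 9 ± 5.55 TPM. PPARGC1A, the coactivator of mitochondrial genes, had 23.2 ± 5.2 and 33.9 ± 9.03 TPM (adjusted p = 0.104, or 0.0132 and higher at 14D after rescaling).

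Collagens and other matrix genes fell in 39 of 60 members and rose in 3 (39 and 5 when adjusted over the list alone), with 11 higher and 35 lower after rescaling. Their median was -1.09 (-0.78 relative to all genes), and 7 of them also stand in other lists. COL14A1 fell from 98.2 ± 16.1 to 4.72 ± 1.2 TPM, VCAN, the proteoglycan versican, from 71.6 ± 15.2 to 3.15 ± 0.182 TPM, COL11A1 from 32.7 ± 5.41 to 1.71 ± 0.654 TPM and COL3A1 from 1411 ± 183 to 635 ± 99.4 TPM (list camera adjusted p = 9.01e-05, adjusted p = 0.268 with an estimated correlation). Fibroblast markers, of which 6 of 17 are shared with other lists, fell in 13 members and rose in 0, also when adjusted over the list alone, with 0 higher and 12 lower after rescaling. Their median was -1.25 (-0.94 relative to all genes, camera adjusted p = 0.000476, adjusted p = 0.231 with an estimated correlation). COL1A2 fell from 1931 ± 278 to 343 ± 31.9 TPM, LUM, the proteoglycan lumican, from 503 ± 67.4 to 116 ± 22.9 TPM and TNMD, a tendon cell protein, from 14.5 ± 1.89 to 1.4 ± 0.943 TPM. Nerve and Schwann cell markers fell in 8 of 12 members and rose in 0, also when adjusted over the list alone, with 0 higher and 6 lower after rescaling. Their median was -0.86 (-0.56 relative to all genes, camera adjusted p = 0.0282, adjusted p = 0.231 with an estimated correlation). ERBB3 fell from 10.1 ± 3.89 to 0.281 ± 0.0553 TPM, SOX10 from 3.48 ± 0.489 to 0.712 ± 0.135 TPM, and PMP22, a myelin protein, from 290 ± 57.4 to 92.7 ± 19.8 TPM. The nerve list's adjusted p was 0.0893, 0.111, 0.0755 and 0.0987 without 1D replicate 1, 2 and 3 and without 14D replicate 2.

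Macrophage markers rose in 9 of 14 members from 1D to 14D and fell in 0, also when adjusted over the list alone, with 11 higher and 0 lower after rescaling. Their median was 1.02 (1.33 relative to all genes, camera adjusted p = 3.23e-06, adjusted p = 0.231 with an estimated correlation). CD74, the invariant chain of antigen presentation, rose from 34.4 ± 21.7 to 463 ± 127 TPM, LAPTM5 from 14.9 ± 0.919 to 59.8 ± 23.6 TPM, IRF8 from 2.18 ± 1.86 to 8.65 ± 2 TPM and CSF1R, the macrophage growth factor receptor, from 10.1 ± 0.697 to 27.4 ± 7.38 TPM. Lymphocyte markers rose in 6 of 12 members and fell in 0, also when adjusted over the list alone, with 8 higher and 0 lower after rescaling. Their median was 0.76 (1.07 relative to all genes, camera adjusted p = 0.000139, adjusted p = 0.231 with an estimated correlation). RAC2 rose from 3.15 ± 1.39 to 13.2 ± 6.43 TPM, BLNK from 9.8 ± 2.55 to 21.3 ± 6.8 TPM, CD247 from 0.409 ± 0.177 to 2.06 ± 0.198 TPM and GZMA from 0.624 ± 0.512 to 4.15 ± 1.43 TPM. Endothelial markers rose in 9 of 19 members and fell in 1, also when adjusted over the list alone, with 14 higher and 0 lower after rescaling. Their median was 0.52 (0.83 relative to all genes, camera adjusted p = 7.98e-05, adjusted p = 0.268 with an estimated correlation). STAB1 rose from 5.85 ± 1.13 to 20.6 ± 6.4 TPM and NOS3, the endothelial nitric oxide synthase, from 14.8 ± 1.92 to 36.9 ± 10.9 TPM, and the receptors TIE1 and TEK rose from 18.4 ± 2.08 to 40.4 ± 12.1 and from 13.4 ± 2.48 to 29.3 ± 8.44 TPM. Adipocyte markers, 4 of 12 of which stand in other lists, rose in 4 members and fell in 0, also when adjusted over the list alone, with 5 higher and 0 lower after rescaling. Their median was 0.57 (0.88 relative to all genes, camera adjusted p = 0.000575, adjusted p = 0.231 with an estimated correlation). ADIPOQ, the fat hormone adiponectin, rose from 43.4 ± 9.31 to 105 ± 12.6 TPM and CIDEA from 5.35 ± 1.01 to 10.1 ± 2.58 TPM.

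Smooth muscle and pericyte markers went both ways from 1D to 14D, with 4 of 12 higher and 3 lower, also when adjusted over the list alone, a median of -0.11 (0.20 relative to all genes) that was 0.23 after rescaling, when 4 were higher and 1 lower, a mean of 0.03 and a camera direction upward (adjusted p = 0.12). RGS5 rose from 52.5 ± 5.15 to 193 ± 60.3 TPM, SMTN from 28 ± 3.18 to 61.3 ± 14 TPM and KCNJ8 from 8.67 ± 1.06 to 18.2 ± 0.724 TPM. DES, desmin, which muscle fibres also express, fell from 1185 ± 135 to 464 ± 106 TPM. Red blood cell markers fell in 2 of 10 members and rose in 0, also when adjusted over the list alone, with 1 higher and 1 lower after rescaling. Their median was 0.12 (0.43 relative to all genes), their mean -0.64, their camera direction upward (adjusted p = 0.697) and their fry direction downward (adjusted p = 0.0384). HBAD was among the members that fell. Atrophy and autophagy genes rose in 11 of 34 members and fell in 5, also when adjusted over the list alone. Their median was 0.34 (0.65 relative to all genes, camera adjusted p = 0.000608, adjusted p = 0.231 with an estimated correlation). After rescaling 15 were higher and 1 lower. FBXO40, a muscle ubiquitin ligase subunit, rose from 1.05 ± 0.0681 to 17.5 ± 13.6 TPM, SQSTM1, the autophagy receptor p62, from 99.3 ± 30.2 to 287 ± 56.6 TPM and TRIM55 from 35 ± 4.27 to 99.7 ± 8.79 TPM. SESN1 fell from 228 ± 109 to 28.9 ± 8.37 TPM. FBXO32, the ubiquitin ligase atrogin-1, had 28.6 ± 17.5 and 56 ± 38.9 TPM (adjusted p = 0.194).

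Immediate-early and heat shock genes, which respond to handling as well as to physiology, rose in 7 of 24 members and fell in 5 from 1D to 14D, also when adjusted over the list alone, with 9 higher and 2 lower after rescaling. Their median was 0.15 (0.46 relative to all genes). The list moved up (camera adjusted p = 0.014, adjusted p = 0.38 with an estimated correlation), with 0.0695 after rescaling, 0.0798 after quantile normalization and 0.0742 without 14D replicate 1. HSP90AA1, a chaperone, rose from 332 ± 11.1 to 1259 ± 156 TPM, NR4A3 from 4.44 ± 1.3 to 17.2 ± 6.06 TPM and DNAJB1 from 4.49 ± 0.838 to 17.1 ± 7.81 TPM. HSPB7 fell from 223 ± 47.3 to 47.5 ± 23.1 TPM. Circadian clock genes fell in 6 of 17 members and rose in 1 (4 and 1 when adjusted over the list alone). Their median was -0.34 (-0.03 relative to all genes), or 0.01 after rescaling, when 3 were lower and 2 higher (camera adjusted p = 0.697). PER3 fell from 24 ± 5.64 to 7.81 ± 3.44 TPM and BHLHE40 from 50.1 ± 7.95 to 25.4 ± 2.73 TPM. HLF fell from 27.8 ± 2.79 to 14.5 ± 6.27 TPM (adjusted p = 0.01, or 0.0948 after rescaling). NR1D2 rose from 14.3 ± 2.22 to 30.6 ± 13.9 TPM (adjusted p = 0.0245), with 0.0504, 0.0843, 0.0845 and 0.0564 without 1D replicate 1, 1D replicate 3, 14D replicate 1 and 14D replicate 2. Cholesterol and lipid synthesis genes fell in 10 of 26 members and rose in 1 (9 and 1 when adjusted over the list alone), with 3 higher and 6 lower after rescaling. Their median was -0.43 (-0.12 relative to all genes, camera adjusted p = 0.558). MVK, SQLE and DHCR7, enzymes of sterol synthesis, fell from 17.1 ± 2.92 to 6.59 ± 1.73, from 2.95 ± 0.929 to 0.872 ± 0.468 and from 4.17 ± 1.37 to 1.43 ± 0.502 TPM.

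From day 14 to day 28 the changes were fewer, and included falls of collagen and growth genes and rises of immediate-early genes. COL1A1 (gene ID 102092022, chromosome 23 from 313540 to 328619) fell from 381 ± 49.4 to 135 ± 24.2 TPM (log2 change -1.50, adjusted p = 0.00814), and COL3A1 fell from 635 ± 99.4 to 267 ± 22.7 TPM (log2 change -1.24, adjusted p = 0.0111). FST, the myostatin antagonist follistatin (gene ID 102091911, chromosome Z from 26242909 to 26250655), fell from 17.6 ± 1.66 to 6.87 ± 0.154 TPM (log2 change -1.24, adjusted p = 0.00814). JUN, an immediate-early transcription factor (gene ID 102092209, chromosome 8 from 12766087 to 12768310), rose from 44.9 ± 12.7 to 287 ± 156 TPM (log2 change 2.55, adjusted p = 0.0111). FOS, its partner in the AP-1 complex, rose from 6.93 ± 9.81 to 291 ± 249 TPM (log2 change 5.64, adjusted p = 0.0145), with adjusted p of 0.0512 without 14D replicate 3 and 0.0621 without 28D replicate 3.

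The other large rises from 14D to 28D were those of FHL2, a LIM domain protein of striated muscle (17.8 ± 18.5 to 219 ± 61.4 TPM), APOLD1, an early-response gene of vessel walls (5.42 ± 3.14 to 75.3 ± 67.7 TPM), DUSP1, a phosphatase of MAP kinases (29.8 ± 18.3 to 274 ± 194 TPM), and DGAT2 (88.2 ± 58 to 526 ± 76.1 TPM, adjusted p = 0.0454). The largest falls were those of SARDH, sarcosine dehydrogenase (16.8 ± 13.3 to 0.696 ± 0.352 TPM), GATM, an enzyme of creatine synthesis (357 ± 83.6 to 65.6 ± 24.8 TPM), SNTB1, a syntrophin (78 ± 48 to 13.1 ± 2.98 TPM), ISM2 (20.9 ± 9.36 to 3.23 ± 1.03 TPM) and PI15 (5.03 ± 3.51 to 0.248 ± 0.168 TPM). In total 169 of 11951 genes passed, 65 higher and 104 lower at 28D, of which 47 and 68 changed at least 2-fold, and 1896 had an unadjusted p below 0.05. The median log2 change of all genes was -0.07, and rescaled values gave 112 higher and 106 lower genes. With the 100 most abundant features left out 74 were higher and 219 lower, and 111 were higher and 89 lower without 14D replicate 2, so the balance of directions varied with the setting. The total was sensitive to single libraries, with 104 genes without 1D replicate 3, 40 without 14D replicate 3, 65 without 28D replicate 1 and 23 without 28D replicate 3. Of the 36 named mRNA genes that passed, COL1A1, COL3A1, FST and JUN passed without each library in turn. With only the 6 libraries of these 2 stages 32 of the 36 calls ended and COL1A1, COL3A1, FST and GATM passed, while JUN had an adjusted p of 0.0611 and FOS 0.0711. The number of named calls lost was 7, 7 and 9 without 1D replicate 1, 2 and 3, 5, 6 and 24 without 14D replicate 1, 2 and 3, and 22, 11 and 30 without 28D replicate 1, 2 and 3, with the highest adjusted p at 0.14.

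Matrix genes fell in 9 of 60 members from 14D to 28D and rose in 0 (21 and 1 when adjusted over the list alone). Their median was -0.32 (camera adjusted p = 2.81e-05, adjusted p = 0.37 with an estimated correlation). LUM fell from 116 ± 22.9 to 39.4 ± 13.2 TPM and COL14A1 from 4.72 ± 1.2 to 1.66 ± 0.52 TPM. Fibroblast markers fell in 4 of 17 members and rose in 0 (7 lower when adjusted over the list alone). Their median was -0.45 (camera adjusted p = 9.07e-06, adjusted p = 0.287 with an estimated correlation), and COL1A2 fell from 343 ± 31.9 to 186 ± 21 TPM. Cell cycle genes fell in 10 of 60 members and rose in 0, and in 41 when adjusted over the list alone, with 15 lower after rescaling. Their median was -0.75 (camera adjusted p = 5.66e-24, adjusted p = 0.287 with an estimated correlation). STMN1, a tubulin-binding protein, fell from 158 ± 20.6 to 70.3 ± 18.9 TPM, MKI67, the proliferation marker Ki-67, from 8.29 ± 2.18 to 3.07 ± 0.169 TPM, KIF11 from 9.26 ± 2.67 to 3.88 ± 0.977 TPM, AURKA from 5.76 ± 1.61 to 2.19 ± 0.18 TPM and CDK1 from 19.4 ± 6.07 to 8.71 ± 1.87 TPM (adjusted p = 0.0439). In the insulin-like growth factor and myostatin axis 4 of 37 members fell and 0 rose (12 and 2 when adjusted over the list alone). Their median was -0.24 (camera adjusted p = 0.000134, adjusted p = 0.265 with an estimated correlation). IGF2BP3 fell from 3.55 ± 1.11 to 0.771 ± 0.215 TPM, IGF2BP2 from 4.23 ± 1.35 to 1.25 ± 0.597 TPM and IGFBP2 from 8.83 ± 0.476 to 4.65 ± 0.196 TPM. IGF1 had 3.9 ± 0.43 and 1.54 ± 0.892 TPM (adjusted p = 0.167) and MSTN 72.5 ± 21.8 and 39.5 ± 3.49 TPM (adjusted p = 0.271). IGF2BP1 had 1.49 ± 0.909 and 0.127 ± 0.0464 TPM (adjusted p = 0.0706, with 0.011 without 14D replicate 2).

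Oxidative genes rose in small numbers from 14D to 28D. Respiratory chain subunits rose in 3 of 40 members and fell in 0, and rose in 22 when adjusted over the list alone, with 7 higher after rescaling. Their median was 0.45 (camera adjusted p = 3.18e-20, adjusted p = 0.265 with an estimated correlation). NDUFA1 rose from 656 ± 94.6 to 1452 ± 210 TPM, ATP5MC1, a subunit of ATP synthase, from 2289 ± 323 to 4083 ± 148 TPM and NDUFB10 from 845 ± 62.5 to 1385 ± 21.4 TPM, and after quantile normalization their adjusted p-values were 0.0847, 0.163 and 0.0807. No tricarboxylic acid cycle gene passed (0 of 24, 4 higher and 2 lower when adjusted over the list alone, and 2 higher after rescaling). The median of the members was 0.35 (camera up, adjusted p = 9.07e-06, adjusted p = 0.349 with an estimated correlation, adjusted p = 0.0605 after quantile normalization). MDH2 had 1151 ± 129 and 1582 ± 110 TPM (adjusted p = 0.13) and IDH2 1124 ± 203 and 1516 ± 77.6 TPM (adjusted p = 0.189). No fatty acid oxidation gene passed either (0 of 36, 3 higher when adjusted over the list alone, and 2 higher after rescaling). The list median was 0.25 (camera up, adjusted p = 1.22e-06, adjusted p = 0.316 with an estimated correlation). ETFA had 587 ± 123 and 923 ± 58.6 TPM (adjusted p = 0.0806, or 0.0474 after rescaling), CPT1A 31.4 ± 4.13 and 23.7 ± 4.03 TPM (adjusted p = 0.396) and LPL 125 ± 51.9 and 166 ± 25.2 TPM (adjusted p = 0.469). FABP3 had 709 ± 732 and 1947 ± 1067 TPM (adjusted p = 0.178, with 0.0187 without 14D replicate 1). MB had 1483 ± 2219 and 11634 ± 1120 TPM, with all 3 libraries of 28D above those of 14D (adjusted p = 0.059, with 0.000644 without 14D replicate 2 and 0.0498 after rescaling). In glycolysis SLC16A1, a lactate transporter, rose from 96.9 ± 9.26 to 191 ± 32.3 TPM, as the only one of 30 members to pass (1 higher and 2 lower when adjusted over the list alone, median -0.22, camera adjusted p = 0.0726). The glycolysis list's adjusted p was 0.00296 without 14D replicate 2, 0.0162 without 28D replicate 3 and 0.0015, downward, after quantile normalization. Of 21 regulators of oxidative genes 0 passed, also when adjusted over the list alone (median -0.01, camera adjusted p = 0.888, mean -0.05, test direction upward). PPARGC1A had 33.9 ± 9.03 and 22.9 ± 5.43 TPM (adjusted p = 0.326), EPAS1 148 ± 47.3 and 162 ± 21 TPM and TFB2M 46.8 ± 7.2 and 41.2 ± 14.6 TPM.

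Of 17 fast-fibre genes 0 passed from 14D to 28D (2 lower when adjusted over the list alone). Their median was -0.32 (camera down, adjusted p = 0.03, adjusted p = 0.37 with an estimated correlation, adjusted p = 0.0735 after rescaling). The fast-fibre list's adjusted p was 0.192 and 0.114 without 14D replicate 1 and 3, and 0.178 and 0.0515 without 28D replicate 1 and 2. ACTA1, skeletal actin, had 23680 ± 3134 and 18063 ± 886 TPM (adjusted p = 0.301), MYL1 16375 ± 1742 and 15049 ± 557 TPM (adjusted p = 0.827) and TNNT3 5707 ± 787 and 5350 ± 265 TPM (adjusted p = 0.856). Of 19 slow and embryonic genes TNNT2, the cardiac troponin T, fell from 9.31 ± 4 to 1.81 ± 1.23 TPM as the only member to pass (6 lower when adjusted over the list alone), with a list median of -0.54 (camera adjusted p = 0.0693, with 0.0393 and 0.0196 without 14D replicate 1 and 2 and 0.0321 after quantile normalization). MYBPC1 had 25.4 ± 35.2 and 1.04 ± 0.584 TPM (adjusted p = 0.134, with 0.0338 without 14D replicate 1). Myogenic regulators fell in 2 of 30 members and rose in 0 (3 and 1 when adjusted over the list alone). Their median was -0.40 (camera adjusted p = 0.00961, adjusted p = 0.296 with an estimated correlation, and 0.131 without 14D replicate 1). MUSK, the receptor of the neuromuscular junction, fell from 5.76 ± 1.11 to 2.35 ± 0.296 TPM (adjusted p = 0.0426, or 0.0521 after rescaling), and NCAM1 fell from 10.3 ± 1.78 to 4.62 ± 0.266 TPM. MYOG had 9.96 ± 4.9 and 7.84 ± 1.19 TPM (adjusted p = 0.876), MYOD1 129 ± 40.7 and 174 ± 30.6 TPM (adjusted p = 0.492), MYF5 21.7 ± 3.93 and 13.6 ± 1.3 TPM (adjusted p = 0.244) and PAX7 5.03 ± 1.27 and 3.17 ± 0.321 TPM (adjusted p = 0.21). Among atrophy genes DDIT4, a stress-induced inhibitor of mTOR, rose from 43.1 ± 28.8 to 180 ± 69.7 TPM and TRIM55 fell from 99.7 ± 8.79 to 58.6 ± 3.33 TPM (adjusted p = 0.03, or 0.052 after rescaling), as 1 riser and 1 faller of 34 (2 and 1 when adjusted over the list alone, camera adjusted p = 0.109, with 0.00112 without 14D replicate 1). FBXO32 had 56 ± 38.9 and 61.1 ± 28 TPM (adjusted p = 0.87).

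Immediate-early and heat shock genes moved up from 14D to 28D by a median of 0.48 (camera adjusted p = 3.14e-09, adjusted p = 0.287 with an estimated correlation), with FOS and JUN as the 2 of 24 members that rose and 0 that fell, and 7 higher and 1 lower when adjusted over the list alone. Endothelial markers rose in 1 of 19 members and fell in 0, also when adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0195, adjusted p = 0.573 with an estimated correlation). Their adjusted p was 0.29 and 0.0516 without 14D replicate 1 and 3, 0.0649 without 28D replicate 2 and 0.0605 after quantile normalization. FLT1, a receptor of vascular endothelial growth factor, rose from 15.8 ± 3.32 to 31.3 ± 3.91 TPM. KCNJ8, a potassium channel of pericytes, rose from 18.2 ± 0.724 to 38.7 ± 3.71 TPM as the only one of 12 smooth muscle markers to pass, also when adjusted over the list alone (median 0.00, camera adjusted p = 0.261). DGAT2 was the only one of 12 adipocyte markers to pass (2 higher when adjusted over the list alone, median 0.08, camera adjusted p = 0.0693), and the adipocyte list's adjusted p was 0.0215 and 0.0465 without 1D replicate 1 and 3 and 0.0341 and 0.0273 without 28D replicate 1 and 3. Macrophage, lymphocyte, red blood cell and nerve markers had 0 members that passed, with medians of -0.18, -0.19, -0.09 and -0.18 and camera adjusted p-values of 0.903, 0.261, 0.732 and 0.261, and adjusted over the list alone 1 nerve marker was lower. The nerve list's adjusted p was 0.0498 without 14D replicate 2. Among these markers CD74 had 463 ± 127 and 540 ± 146 TPM, BLNK 21.3 ± 6.8 and 23 ± 4.29 TPM, TFRC 349 ± 221 and 370 ± 116 TPM and PMP22 92.7 ± 19.8 and 70.5 ± 3.9 TPM.

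Ribosomal proteins had 0 of 64 members that passed from 14D to 28D, also when adjusted over the list alone, and a median of 0.07. Their list test pointed up as deposited (camera adjusted p = 0.00564, adjusted p = 0.663 with an estimated correlation) and down after quantile normalization (adjusted p = 0.00715, median -0.14), and its adjusted p was 0.29 without 14D replicate 1 and 0.45 without 28D replicate 1. RPL35 had 2447 ± 278 and 2736 ± 282 TPM and RPL27 2273 ± 257 and 2478 ± 309 TPM. Proteasome, circadian clock and cholesterol synthesis genes had 0 members that passed, also when adjusted over the list alone, with medians of 0.04, -0.22 and 0.03 and camera adjusted p-values of 0.109, 0.0872 and 0.109. The adjusted p of the proteasome list was 0.0393 without 14D replicate 1. That of the clock list was 0.0156 without 14D replicate 2 and 0.0124 without 28D replicate 3, and that of the cholesterol list was 0.0086 and 0.0382 without the same libraries. PSMB4 had 188 ± 17.8 and 267 ± 27.7 TPM (adjusted p = 0.107), CRY1 74.8 ± 7.04 and 78.9 ± 10.7 TPM (adjusted p = 0.871) and FDPS, farnesyl diphosphate synthase, 65.5 ± 12.3 and 101 ± 5.19 TPM (adjusted p = 0.0826, or 0.0413 after rescaling).

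**Figure D3:**
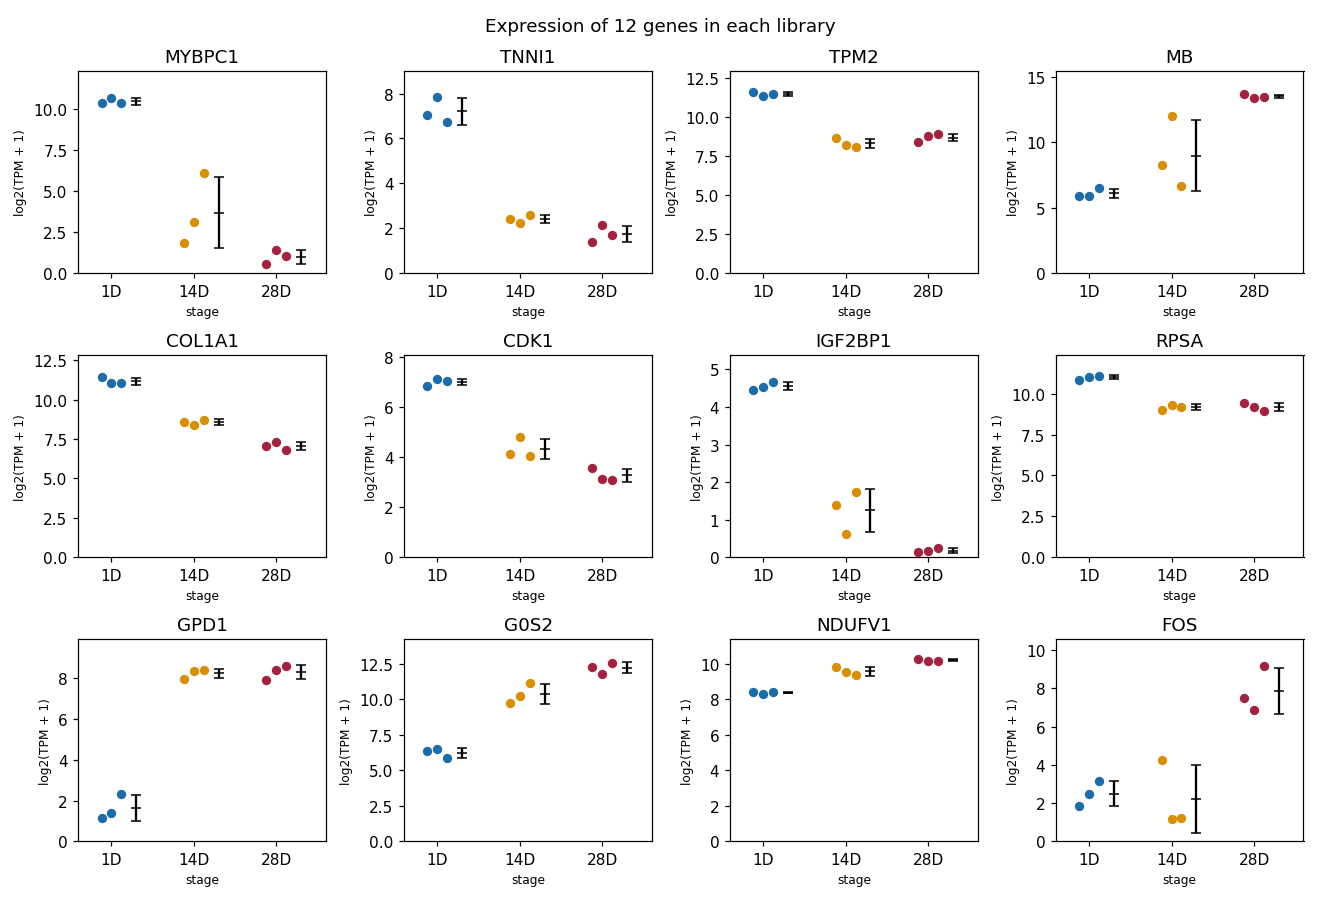
Expression of 12 named genes as log2(TPM + 1) (vertical axis) at each stage (horizontal axis); coloured points are the 3 libraries of a stage, and black marks are their mean ± SD on the log2 scale. Myoglobin (MB) at 14D ranged from 100 to 4042 TPM between libraries, while at 28D it lay between 10763 and 12898 TPM.

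From day 1 to day 28 transcripts of myoglobin and most measured NDUF, SDH and ATP synthase subunits rose. This comparison was added after the column names were seen. MB rose from 68.7 ± 17.6 to 11634 ± 1120 TPM (log2 change 7.41, adjusted p = 0.000123), DGAT2 from 1.74 ± 1.63 to 526 ± 76.1 TPM (log2 change 7.75, adjusted p = 3.71e-06), and G0S2, an inhibitor of fat breakdown, from 75.2 ± 16.2 to 4876 ± 1292 TPM (log2 change 5.99, adjusted p = 5.82e-07). MYBPC1 fell from 1404 ± 206 to 1.04 ± 0.584 TPM (log2 change -9.46, adjusted p = 6.53e-06). GPD1 and FOS completed the 5 largest rises (to 321 ± 71.8 and 291 ± 249 TPM), and HBAD, PTN, MAT1A, which makes S-adenosylmethionine, and THBS4 completed the 5 largest falls, with MAT1A going from 267 ± 71.7 to 2.4 ± 0.64 TPM. A total of 7209 genes passed, 1960 higher and 5249 lower at 28D, of which 1006 and 2884 changed at least 2-fold. The median log2 change was -0.38, or -0.01 after rescaling, and rescaled values gave 3404 higher and 3538 lower genes and quantile normalization 3440 and 3495, with the same centring.

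Respiratory chain subunits rose in 35 of 40 members from 1D to 28D and fell in 0, also when adjusted over the list alone, with 38 higher and 0 lower after rescaling. Their median was 1.03 (1.42 relative to all genes, camera adjusted p = 1e-18, adjusted p = 0.216 with an estimated correlation). NDUFV1 rose from 332 ± 11.3 to 1166 ± 46.7 TPM and ATP5F1B, the catalytic subunit of ATP synthase, from 1007 ± 69.1 to 2930 ± 322 TPM. Tricarboxylic acid cycle genes rose in 18 of 24 members and fell in 2, also when adjusted over the list alone, with 21 higher and 1 lower after rescaling. Their median was 0.92 (1.30 relative to all genes, camera adjusted p = 3.05e-10, adjusted p = 0.216 with an estimated correlation). IDH2 rose from 483 ± 25.3 to 1516 ± 77.6 TPM. PDK4 rose from 338 ± 206 to 1185 ± 590 TPM (adjusted p = 0.0273), with 0.105, 0.0643 and 0.0941 without 1D replicate 1, 28D replicate 1 and 28D replicate 3. Fatty acid oxidation genes rose in 18 of 36 members and fell in 4, also when adjusted over the list alone, with 24 higher and 4 lower after rescaling. Their median was 0.43 (0.81 relative to all genes, camera adjusted p = 9.08e-05, adjusted p = 0.258 with an estimated correlation). ACADM, the medium-chain acyl-CoA dehydrogenase, rose from 255 ± 36.5 to 602 ± 50.7 TPM and ETFB from 33.3 ± 27.1 to 114 ± 18 TPM. CPT1A had 23.7 ± 4.03 TPM at 28D (adjusted p = 0.149), FABP3 1947 ± 1067 TPM (adjusted p = 0.66) and LPL 166 ± 25.2 TPM (adjusted p = 0.246, with 0.0258 after rescaling and 0.0468 without 14D replicate 3), and none of these passed. Glycolysis and glycogen genes rose in 21 of 30 members and fell in 4 (21 and 5 when adjusted over the list alone), with 24 higher and 1 lower after rescaling. Their median was 1.14 (1.52 relative to all genes, camera adjusted p = 2.25e-10, adjusted p = 0.122 with an estimated correlation). ALDOC rose from 268 ± 4.75 to 1921 ± 457 TPM and PPP1R3C from 1.94 ± 0.0508 to 50.1 ± 22.5 TPM. Regulators of oxidative genes rose in 4 of 21 members and fell in 6, also when adjusted over the list alone, and 10 were higher and 4 lower after rescaling. Their median as deposited was 0.09 (0.47 relative to all genes, camera adjusted p = 0.0563). ESRRB rose from 5.6 ± 0.838 to 35.4 ± 11.3 TPM, and PPARA fell (log2 change -2.02, adjusted p = 0.000627). PPARGC1A did not pass (23.2 ± 5.2 and 22.9 ± 5.43 TPM, adjusted p = 0.945).

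Cell cycle genes fell in 59 of 60 members from 1D to 28D and rose in 0, also when adjusted over the list alone, with 0 higher and 59 lower after rescaling. Their median was -2.71 (-2.32 relative to all genes, camera adjusted p = 1.84e-17, adjusted p = 0.216 with an estimated correlation). SPC25, a kinetochore protein, fell from 83.1 ± 11.3 to 4.07 ± 2.5 TPM, CKAP2 from 108 ± 12.3 to 7.17 ± 2.78 TPM and CDK1 from 127 ± 11.6 to 8.71 ± 1.87 TPM. Ribosomal proteins fell in 61 of 64 members and rose in 2, also when adjusted over the list alone, with 2 higher and 56 lower after rescaling. Their median was -1.33 (-0.95 relative to all genes, camera adjusted p = 1.18e-09, adjusted p = 0.311 with an estimated correlation), with RPL3 going from 1420 ± 174 to 381 ± 47.7 TPM and RPL3L from 5.9 ± 2.87 to 236 ± 20.8 TPM. Proteasome subunits fell in 28 of 31 members and rose in 0, also when adjusted over the list alone, with 2 higher and 22 lower after rescaling. Their median was -1.10 (-0.72 relative to all genes, camera adjusted p = 1.28e-05, adjusted p = 0.216 with an estimated correlation), and PSMD5 fell from 32.3 ± 1.73 to 10.2 ± 0.716 TPM. Matrix genes fell in 37 of 60 members and rose in 6, also when adjusted over the list alone, with 10 higher and 35 lower after rescaling. Their median was -1.64 (-1.26 relative to all genes, camera adjusted p = 9.08e-05, adjusted p = 0.258 with an estimated correlation). VCAN fell from 71.6 ± 15.2 to 1.45 ± 0.379 TPM and COL3A1 from 1411 ± 183 to 267 ± 22.7 TPM. Fibroblast markers fell in 13 of 17 members and rose in 0, also when adjusted over the list alone, with 0 higher and 13 lower after rescaling. Their median was -1.87 (-1.49 relative to all genes, camera adjusted p = 9.08e-05, adjusted p = 0.216 with an estimated correlation), and COL1A1 fell from 2329 ± 389 to 135 ± 24.2 TPM. The insulin-like growth factor and myostatin axis fell in 25 of 37 members and rose in 4, also when adjusted over the list alone, with 6 higher and 21 lower after rescaling. Their median was -0.97 (-0.59 relative to all genes, camera adjusted p = 0.00716, adjusted p = 0.216 with an estimated correlation). IGF2BP1 fell from 22.5 ± 1.72 to 0.127 ± 0.0464 TPM and IGF1 from 27.1 ± 10.8 to 1.54 ± 0.892 TPM. MSTN had 39.5 ± 3.49 TPM at 28D (adjusted p = 0.0691, with 0.00161 without 1D replicate 2).

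Slow and embryonic sarcomere genes fell in 14 of 19 members from 1D to 28D and rose in 2, also when adjusted over the list alone, with 2 higher and 13 lower after rescaling. Their median was -1.49 (-1.11 relative to all genes, camera adjusted p = 0.0132, adjusted p = 0.216 with an estimated correlation). TNNI1 fell from 156 ± 67.7 to 2.4 ± 0.882 TPM. TNNC1 instead had 565 to 1331 TPM at 1D and 5917 to 6920 TPM at 28D. Fast-fibre genes split into 7 of 17 that rose and 5 that fell, also when adjusted over the list alone, with 10 higher and 4 lower after rescaling. Their median was 0.20 (0.59 relative to all genes), their mean -0.00, with a camera direction upward (adjusted p = 0.0486, adjusted p = 0.3 with an estimated correlation) and a fry direction downward (adjusted p = 0.952). The fast-fibre call ended with a pseudocount of 0.1 (0.0518), after rescaling (0.0737) and quantile normalization (0.854). It also ended without 1D replicate 1 or 2 (0.138, 0.0643) or 28D replicate 2 or 3 (0.0693, 0.0801). TNNC2, the fast troponin C, fell from 9464 ± 742 to 4098 ± 693 TPM and MYOZ1 rose from 544 ± 180 to 1160 ± 82.3 TPM. TNNT3 did not pass (5350 ± 265 TPM at 28D, adjusted p = 0.472, or 0.0251 and higher after rescaling). Myogenic regulators fell in 20 of 30 members and rose in 2, also when adjusted over the list alone, with 2 higher and 15 lower after rescaling. Their median was -0.99 (-0.61 relative to all genes, camera adjusted p = 0.0225, adjusted p = 0.245 with an estimated correlation). PAX7 fell from 8.07 ± 1.02 to 3.17 ± 0.321 TPM and MYF5 from 31.4 ± 12.5 to 13.6 ± 1.3 TPM. MYOD1 (174 ± 30.6 TPM at 28D, adjusted p = 0.612) and MYOG (7.84 ± 1.19 TPM, adjusted p = 0.328) did not pass. Atrophy and autophagy genes rose in 12 of 34 members and fell in 4, also when adjusted over the list alone, with 19 higher and 3 lower after rescaling. Their median was 0.42 (0.80 relative to all genes, camera adjusted p = 0.00027, adjusted p = 0.216 with an estimated correlation). KLHL38 rose from 2.64 ± 0.77 to 8.4 ± 2.81 TPM. FBXO32 had 61.1 ± 28 TPM at 28D (adjusted p = 0.0946, with 0.0414 after rescaling and 0.0329, 0.0496 and 0.0476 without 1D replicate 2, 14D replicate 1 and 28D replicate 2).

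Macrophage markers rose in 8 of 14 members from 1D to 28D, lymphocyte markers in 6 of 12, endothelial markers in 12 of 19 and adipocyte markers in 5 of 12, and 0, 0, 2 and 0 members fell, with the same counts adjusted over the list alone. After rescaling 12, 6, 15 and 8 members were higher and 0, 0, 2 and 0 lower. Their medians were 0.80, 0.61, 1.04 and 0.55 (1.18, 0.99, 1.42 and 0.93 relative to all genes), with camera adjusted p-values of 4.39e-05, 0.00224, 1.95e-05 and 0.000379 and, with an estimated correlation, adjusted p-values of 0.258, 0.216, 0.253 and 0.216. CD74 rose from 34.4 ± 21.7 to 540 ± 146 TPM, CD8A from 0.134 ± 0.113 to 1.17 ± 0.331 TPM, TEK from 13.4 ± 2.48 to 39.1 ± 6.86 TPM and ADIPOQ from 43.4 ± 9.31 to 176 ± 19.8 TPM. LYVE1, a lymphatic vessel marker, fell from 4.89 ± 0.172 to 1.07 ± 0.454 TPM. PLIN1, a coat protein of lipid droplets, rose from 4.17 ± 4.11 to 10.6 ± 3.43 TPM (adjusted p = 0.0216), with 0.0656 and 0.0802 without 1D replicate 2 and 3 and 0.0573 and 0.0732 without 28D replicate 1 and 2. Smooth muscle markers split into 3 of 12 higher and 3 lower, also when adjusted over the list alone (median -0.14, 0.24 relative to all genes, 0.26 after rescaling with 4 higher and 2 lower, mean 0.09, camera adjusted p = 0.121), with RGS5 going from 52.5 ± 5.15 to 265 ± 11.6 TPM. Nerve markers fell in 10 of 12 members and rose in 0, also when adjusted over the list alone, with 0 higher and 7 lower after rescaling. Their median was -1.21 (-0.83 relative to all genes, camera adjusted p = 0.0183, adjusted p = 0.216 with an estimated correlation, and 0.0582 and 0.0643 without 1D replicate 1 and 2). Red blood cell markers fell in 4 of 10 members and rose in 0, also when adjusted over the list alone. Their median was 0.12 (0.50 relative to all genes), their mean -0.72, with a camera direction upward (adjusted p = 0.812) and a fry direction downward (adjusted p = 0.0105). After rescaling 3 were higher and 2 lower. SPTB fell from 74 ± 5.13 to 40.7 ± 1.97 TPM and GYPC from 64.3 ± 11 to 38.1 ± 8.43 TPM, with adjusted p-values of 0.104 and 0.128 after rescaling.

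Immediate-early and heat shock genes rose in 13 of 24 members from 1D to 28D and fell in 3, also when adjusted over the list alone, with 14 higher and 1 lower after rescaling. Their median was 1.14 (1.53 relative to all genes, camera adjusted p = 1.27e-05, adjusted p = 0.216 with an estimated correlation). KLF2 rose from 23.3 ± 6.74 to 218 ± 115 TPM, ATF3 from 18.8 ± 4.67 to 163 ± 89.2 TPM and DNAJB1 from 4.49 ± 0.838 to 22.5 ± 1.76 TPM. Circadian clock genes fell in 9 of 17 members and rose in 0, also when adjusted over the list alone (median -0.57, -0.19 relative to all genes, camera adjusted p = 0.283). After rescaling 4 were lower and 2 higher. PER3 fell from 24 ± 5.64 to 3.99 ± 0.523 TPM and BHLHE40 from 50.1 ± 7.95 to 23.6 ± 5.96 TPM. BHLHE41 fell from 7.5 ± 3.31 to 2.44 ± 0.876 TPM (adjusted p = 0.0132), with 0.0531 after rescaling and 0.054 and 0.0551 without 1D replicate 1 and 2. Cholesterol synthesis genes fell in 11 of 26 members and rose in 4 (10 and 4 when adjusted over the list alone), with 5 lower and 5 higher after rescaling. Their median as deposited was -0.42 (-0.04 relative to all genes, camera adjusted p = 0.942). FDFT1, squalene synthase, rose from 20.1 ± 3.83 to 42.8 ± 3.17 TPM.

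The lncRNA table showed the same uneven timing. From 1D to 14D 1988 of 8685 transcripts passed, 443 higher and 1545 lower, of which 407 and 1481 changed at least 2-fold. After rescaling 670 were higher and 1088 lower, and after quantile normalization 865 were higher and 858 lower. The median log2 change of all lncRNA transcripts was -0.45, and -0.17 after rescaling. The transcript listed as G18222 rose from 0.357 ± 0.0601 to 27.4 ± 9.39 TPM, that of TMIGD2 from 0.658 ± 1.14 to 22.9 ± 5.82 TPM, and that of RASAL3 was listed at 0 in all 3 libraries of 1D and had 5.37 ± 0.911 TPM at 14D. The reference calls the genes of both these IDs protein-coding, and whether the entries are noncoding transcripts or the coding genes themselves is not known. LOC110354925 had 38 ± 21.3 TPM at 1D and was listed at 0 in all 3 libraries of 14D, GeneID:110355760 fell from 60.3 ± 38.6 to 0.102 ± 0.121 TPM and GeneID:110357310 from 143 ± 30.4 to 0.777 ± 0.818 TPM. Without 1D replicate 1, 2 or 3 the count was 966, 984 or 1056.

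From 14D to 28D 11 lncRNA transcripts passed, 6 higher and 5 lower, all changed at least 2-fold, and 749 had an unadjusted p below 0.05. GeneID:110365575 was listed at 0 in all 3 libraries of 14D and had 13.9 ± 2.42 TPM at 28D, GeneID:110364308 rose from 0.263 ± 0.455 to 9.71 ± 1.99 TPM and LOC102093299 from 2.48 ± 0.664 to 82.5 ± 53.9 TPM. G22819 fell from 16.6 ± 7.84 to 0.919 ± 0.251 TPM (adjusted p = 0.00965). GeneID:110360525 with 2.16 ± 1.9 TPM and LOC110357280 with 1.41 ± 0.829 TPM at 14D were listed at 0 in all 3 libraries of 28D. G22819 passed without each library in turn, but its adjusted p was 0.109 with only the 6 libraries of the 2 stages. The other 5 each lost the call without at least 1 library, with adjusted p up to 0.154, and the count was 2 without 1D replicate 1, 1D replicate 3 or 28D replicate 1, 3 without 14D replicate 3, and 6 and 4 without 28D replicate 2 and 3.

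From 1D to 28D 2602 lncRNA transcripts passed, 646 higher and 1956 lower, of which 591 and 1882 changed at least 2-fold, with a median log2 change of -0.52 over all transcripts, -0.19 after rescaling, when 955 were higher and 1416 lower. Quantile normalization gave 1170 higher and 1175 lower. G15189 rose from 0.306 ± 0.19 to 30 ± 4.69 TPM and LOC102093299 from 1 ± 0.532 to 82.5 ± 53.9 TPM. G22572, listed at 0 in all 3 libraries of 1D, had 9.84 ± 3.36 TPM at 28D. GeneID:110357310 fell from 143 ± 30.4 to 0.0473 ± 0.082 TPM, and GeneID:110356159 and LOC110354925, with 37.1 ± 3.22 and 38 ± 21.3 TPM at 1D, were listed at 0 in all 3 libraries of 28D. Without 1D replicate 1, 2 or 3 the count was 1577, 1619 or 1667.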

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

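The settings beside the chosen one were fixed before the data were examined, except the 28D vs 1D comparison and those stated above as chosen later. Where a setting changed a result, the cause was not tested. The mRNA count of 169 genes for 28D vs 14D moved with many settings: it was 21 with only the 6 libraries of these stages, 450 with arrayWeights, 1126 when adjusted over the comparisons jointly, 293 with the 100 most abundant features left out, and 23 to 204 when each library was left out. A change of at least 2-fold kept 3020 mRNA genes for 14D vs 1D and 3890 for 28D vs 1D. The 11 lncRNAs of 28D vs 14D became 17 with a pseudocount of 1, 1 with only the 6 libraries, 174 when adjusted jointly, and 2 to 15 when each library was left out. Leaving out each library gave 966 to 2109 lncRNAs for 14D vs 1D, 1577 to 2600 for 28D vs 1D and 1050 to 2189 for the F test, and a stricter filter gave 1723 for 28D vs 1D. Among list results that passed in the chosen or the alternative test, the direction of 5 changed. With the fry test of limma they were fatty acid oxidation (adjusted p = 0.698) and red blood cell markers (adjusted p = 0.0384) for 14D vs 1D, and fast-fibre genes (adjusted p = 0.952) and red blood cell markers (adjusted p = 0.0105) for 28D vs 1D, and with quantile normalization ribosomal proteins for 28D vs 14D (adjusted p = 0.00715). No named gene changed direction. Over all settings the list tests kept direction and side of the threshold in 1002 cases, fell short of it in 95 and newly passed it in 23, and the named genes did so in 6634, 300 and 44 cases. Without counts, the limit that depth sets on low values could not be computed.

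With the replicate number as a block the 28D vs 14D count was 96 for mRNA and 1 for lncRNA. The libraries only share a replicate number between stages, and no label says that they were paired. After stage means were taken out, the correlation of 2 libraries that share a number ranged from -0.0719 to 0.0466 in the mRNA table and from -0.055 to 0.0204 in the lncRNA table, and 1 of 9 libraries in the mRNA table and 2 of 9 in the lncRNA table correlated best with their own number.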

Other observations

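Both tests of TPM scaling below, and the 28D vs 1D comparison used for neighbouring genes, were chosen after results had been seen. The excess of mRNA genes that were lower at 14D than at 1D (median log2 change -0.31) was set against the scaling of TPM. With TPM set to 1000000 within the mRNA table the median was -0.18 (-0.23 to -0.15 with each library left out, 2099 higher and 3952 lower). This setting takes the lncRNA share out of the scaling, so the larger lncRNA share can account for only part of the shift. The -0.18 that remained cannot come from that share. With the 100 most abundant features of both tables left out, 87 mRNA genes and 13 lncRNAs, the median was -0.04 (-0.07 to -0.02 with each library left out), with 2627 genes higher and 3235 lower. These features held 35.8% ± 0.714 of TPM at 1D, 47.9% ± 3.73 at 14D and 45.4% ± 1.26 at 28D (SD, n = 3), so abundant transcripts taking a larger share may account for most of the 14D shift. For 28D vs 1D the same setting left the median at -0.18, against -0.38 as deposited, with 2644 genes higher and 4159 lower, so a large part of that shift remained. A true loss of RNA per cell stays open because TPM holds no absolute amount.

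The rise of immediate-early and heat shock genes from 14D to 28D could reflect age, handling of the birds or time before freezing. It was not carried by 28D replicate 3 alone, since without that library the list had a camera p of 8.8e-07 (adjusted p = 5.5e-06, and adjusted p = 0.321 with an estimated correlation). Within stages the members' mean pairwise correlation was 0.251, at percentile 99.8 of 1000 matched random lists (median 0.0886). Estimated correlations of the lists spanned -0.0293 to 0.624, so 0.251 cannot show a state of single samples. The list's median deviation from each gene's mean was -0.41, -0.45 and -0.46 in the 1D libraries, 0.19, -0.25 and -0.48 at 14D, and 0.35, 0.28 and 0.78 at 28D. Handling and age cannot be separated, as the labels give no time of sampling.

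Between 1D and 28D the log2 changes of lncRNAs and of their nearest tested protein-coding gene had a Spearman correlation of 0.24 over 1293 pairs. Its permutation p was 0.0001 (adjusted p = 0.000133), the smallest that 10000 permutations can give. This correlation was 0.31 over 448 overlapping pairs, 0.27 over 445 within 10 kb and 0.13 over 400 further apart (permutation p = 0.0111). The last value argues against reads shared by adjoining gene models as the whole cause, but the higher close values leave room for a part. Where both passed, 179 of 218 pairs moved the same way, against 152 from the margins (47 of 60 against 42.6 beyond 10 kb). Shared regulation of neighbours is a hypothesis that these values do not separate from a shared chromatin or tissue change.

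Other groupings of the same libraries were compared with the real stages. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05, and only the real one reached its count. The real value and the highest other were 6311 and 0 mRNA genes for 14D vs 1D, 169 and 5 for 28D vs 14D and 7209 and 0 for 28D vs 1D, and 1988 and 5, 11 and 9, and 2602 and 7 lncRNAs. For the F test 1 of 100 splits, the real one, gave as many, with 6985 mRNA genes against a highest other of 6595 and 2286 lncRNAs against 2144. Every other split of 3 with 3 mixes the stages and so raises the spread, which builds in low counts. F test splits can keep the 1D libraries together, which was not examined, so neither test measures chance.

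A few lncRNA entries held much of that table. The entry G22683 had 35379 ± 1943, 62354 ± 8313 and 45212 ± 7985 TPM at 1D, 14D and 28D, G22941 had 4857 ± 1501, 31386 ± 7724 and 28950 ± 1662 TPM, and G22763 had 7657 ± 1557, 20077 ± 4916 and 22913 ± 5002 TPM (SD, n = 3). The 4 most abundant entries held 34.1%, 31.9% and 35.8% of the lncRNA total in the 1D libraries, 59.6%, 52.1% and 61.6% at 14D and 49.2%, 53.1% and 55.8% at 28D. PTMA, which the reference calls protein-coding, stood in the lncRNA table with 6688 ± 511, 2966 ± 758 and 2892 ± 235 TPM. In the mRNA table the 14D libraries differed from each other in genes chosen after their values were seen, with MB at 307, 4042 and 100 TPM, FABP3 at 1549, 369 and 210 TPM and MYBPC1 at 2.61, 7.62 and 65.9 TPM.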
